A study of Mus musculus with 4 samples.

How the data were processed

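Gene expression was measured in 4 samples of mouse spleen-derived CD4+ cells, 2 from wild type mice and 2 from CD4+ lymphoma of homozygous Tet2 gene trap mice, each on 1 single-channel array. Per the labels' protocols, red cells of a spleen suspension were lysed, CD4+ cells were bound by a biotinylated antibody and collected on magnetic columns, total RNA was extracted and material was labelled with biotin using an Affymetrix expression labelling kit. A magnetic column enriches cells that carry CD4 and does not exclude other CD4-bearing cells, such as some dendritic cells, or cells held on the column unspecifically. No purity was given in the sources used here.

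The values are the authors' deposited intensity values, 1 per probe set and array, on a linear scale. Per the submitters' processing notes they were made with Affymetrix Expression Console. The summarisation method, the background correction, the normalization and the software version are not given in the sources used here. The 35556 values of each array ranged from 2.50 at the lowest to 18153 at the highest, none was negative or missing, and the arrays had similar but not identical quantiles. No detection calls were used here, so no probe set could be set against background, and fold changes of dim probe sets can be understated.

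From these values, log2 was taken without a pseudocount or filter. Probe sets were named from the platform annotation of GEO, of which 21789 had 1 gene symbol, 1621 had several and 12146 were not listed. Of the 21789, 21698 matched a RefSeq gene by identifier and 0 symbols changed through that table, while 91 kept the annotation's name. Where a gene had several probe sets (999 genes), the one with the highest mean over all arrays was used, which left 19938 genes. Genes that had no probe set with a single symbol have no value. Genome positions are not given because the build behind the array annotation is not named.

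Lymphoma was compared with wild type in limma 3.58.1 (R 4.3.3) with group as the only term, a variance trend on mean level in eBayes, two-sided tests and Benjamini-Hochberg adjustment over the 19938 genes. There were 2 residual degrees of freedom and 4.24 prior degrees of freedom, and the median SE of a log2 fold change was 0.20. An adjusted p under 0.05 counted as a call. Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives except where stated otherwise. They cover T helper subsets, T cell states, cell division, metabolism, signalling, sex-linked genes, receptor and immunoglobulin segments and the other cell types of the spleen. Of 36 lists, 35 had at least 3 measured genes and were tested with limma's camera (preset correlation 0.01), with camera at an estimated correlation and with fry, each adjusted over the 35 lists. The camera tests compare a list with other genes, and fry does not. The T cell receptor beta V list had 1 measured segment and was not tested.

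Named genes are Tet2, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, without predicted or non-coding models, receptor and immunoglobulin segments and sex-linked genes, then up to 4 called members of each list by size (or 2 given as values where none was called), and 10 genes named beforehand, of which 1 is not reported here. Groups of 2 and 2 arrays often fail to overlap by chance, so this condition adds little. Genes of the sex-linked list are given among the flagged results.

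In simulated data with the real genes, 200 of 19938 were changed for lymphoma against wild type. Noise was drawn from the fitted variances, independently for each gene and alike in both groups. The procedure was tested on these data. It recovered 1% of genes changed by 1 log2 unit and 78% of those changed by 2 log2 units, with 4 unchanged genes called, and made 0.2 calls on average when nothing was changed. Simulated lists of 15 genes shifted by 0.5 log2 units were called in 10 of 10 cases with the preset correlation. With an estimated correlation 0 of 10 were called. Of 20 unshifted lists, 0 were called with the preset correlation. Genes of the real lists can vary together (estimated correlation 0.852 for mitosis), so these list counts do not measure false calls on such lists.

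Alternatives were quantile normalization, subtraction of array medians, leaving out the lowest tercile of mean level or the values below the median, no variance trend, a robust trend, averaging of probe sets, the replicate number as a block, array weights, leaving out each array, other thresholds and testing all probe sets. Leaving out an array leaves 1 sample in a group, which is then assumed to vary like the other group. A covariate for Y-linked expression was added after seeing the data. Figures were drawn with matplotlib 3.10.9.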

Results

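Total RNA from spleen-derived CD4+ cells of C57BL/6 mice was profiled on 4 Affymetrix gene arrays. The design compared 2 groups with 2 arrays in each. One group was CD4+ lymphoma that had developed in the spleen of mice homozygous for a gene trap in Tet2, a dioxygenase that oxidises 5-methylcytosine in DNA. The other was CD4+ splenocytes of wild type mice. A gene trap is an inserted cassette that interrupts a gene's transcript. The comparison addresses how expression in CD4+ lymphoma arising without intact Tet2 differs from that in normal CD4+ cells. Genotype and malignancy differ together between the groups, so effects of Tet2 loss and of the tumour cannot be told apart. The number of arrays limits the precision of every value. The labels number the samples without saying how many animals they came from, so limma p-values of single genes measure the spread between these samples. Camera p-values at the preset correlation set a list against other genes and assume nearly independent genes. They do not measure how a list's mean varies between samples. The mitosis list, with an estimated correlation of 0.852, had a camera adjusted p of 1e-16 at the preset correlation. It had 0.392 at the estimated correlation and 0.137 with fry.

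The arrays were similar in overall signal. The median intensity over 35556 probe sets was 142 and 141 on the wild type arrays and 138 and 130 on the lymphoma arrays. Across probe sets, which are not independent replicates, log2 values correlated at r = 0.98 between the wild type arrays and r = 0.97 between the lymphoma arrays. The correlations between a wild type and a lymphoma array lay between 0.95 and 0.97.

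Tet2 itself had an intensity of 998 ± 25.6 (SD, n = 2) on the wild type arrays and 497 ± 140 (SD, n = 2) on the lymphoma arrays. Both lymphoma values, 596 and 399, lay below both wild type values, 980 and 1016. The log2 difference was -1.03 (SE 0.24), a 2.05-fold lower signal, with an adjusted p of 0.077 (limma, Benjamini-Hochberg), so it did not pass the threshold of 0.05. Without lymphoma array 1 the difference was -1.32 (adjusted p = 0.0016), and over all alternative settings the adjusted p lay between 0.0016 and 0.41. The position of the gene trap relative to the probes of this probe set is not given in the sources used here, so how far the value checks the genotype label is unknown.

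Among 19938 genes tested, 362 were higher and 490 were lower in lymphoma at an adjusted p under 0.05 in limma, together 4.27% of the genes. Of these, 319 rose and 468 fell at least 2-fold, 68 rose and 159 fell at least 4-fold, and 15 rose and 45 fell at least 8-fold. The largest rise was that of Vwde, by 4.99 on the log2 scale (SE 0.18, 31.8-fold, adjusted p = 0.00085). It was followed by Tmem45a with 4.62 and by Cd109, a surface glycoprotein anchored to the membrane by a lipid, with 4.39. Vat1l rose by 4.25, Aoc1, a diamine oxidase, by 4.11, and Ak4, a mitochondrial adenylate kinase, by 3.88, or by 2.53 (adjusted p = 0.0025) with its probe sets averaged. Olfr60, annotated as an olfactory receptor, rose by 3.78, Vdr, the vitamin D receptor, by 3.68, Tmem63c by 3.54 and Dgki, a diacylglycerol kinase, by 3.20. The largest fall outside the immunoglobulin segments was that of Dapl1, by 5.20 on the log2 scale (SE 0.19, 36.8-fold, adjusted p = 0.00085). Klri1, a lectin-like receptor of natural killer cells, fell by 4.97 and Jchain, which joins polymeric immunoglobulins, fell by 4.53. The next log2 differences were -4.40 for the dendritic cell lectin Cd209a, -4.39 for the complement receptor Cr2 and -4.37 for the IgE receptor Fcer2a. Those of the fatty acid desaturase Scd1 (-4.21), the adhesion receptor Cd226 (-3.91), Adam23 (-3.86) and the IgM receptor Fcmr (-3.75) also passed. With a robust variance trend the calls on Aoc1 (adjusted p = 0.142), Olfr60 (0.209) and Jchain (0.241) were lost in limma.

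The counts depended on which arrays set the spread. With 1 wild type array left out, the spread came from the lymphoma pair alone and no gene passed in limma, either without wild type array 1, where 1418 genes were higher and 890 lower at an unadjusted p under 0.05, or without wild type array 2, where these counts were 929 and 1120. With lymphoma array 1 left out 889 genes rose and 843 fell, and with lymphoma array 2 left out 1057 rose and 795 fell. All 852 called genes kept their sign in each of these 4 fits. For genes whose groups do not overlap, leaving out 1 array cannot change the sign, so this is no separate check. With a lymphoma array left out, 1 lymphoma array stood for the group and the spread came from the wild type pair alone. Genes or lists said to pass in such fits, throughout this text, are not shown to differ in lymphoma as a group. The calls on single genes given here and in the following paragraphs hold with all 4 arrays, and none of them passed when either wild type array was left out.

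**Figure D1:**
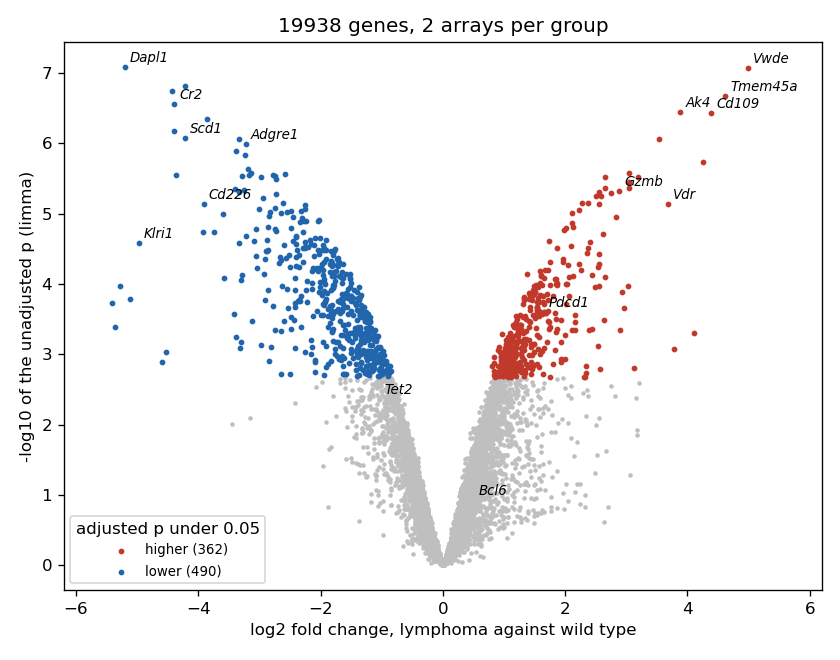
Each point is 1 of 19938 genes, with the log2 fold change of lymphoma over wild type (2 arrays each) on the x axis and minus log10 of the unadjusted limma p on the y axis. Red points mark the 362 genes higher and blue points the 490 genes lower at an adjusted p under 0.05, with Vwde and Dapl1 highest on either side.

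Follicular helper T cells are the CD4+ cells that assist B cells in germinal centres. Of 21 measured genes of the follicular helper list, 5 rose, none fell and 16 did not pass. The inhibitory receptor Pdcd1 rose by 1.65 on the log2 scale (SE 0.22, 3.14-fold, adjusted p = 0.014 in limma), from 10.44 ± 0.24 (SD, n = 2) to 12.08 ± 0.33 (SD, n = 2). The high mobility group factor Tox2 rose 2.29-fold, the costimulatory receptor Icos by 1.19 on the log2 scale and the related factor Tox by 0.96. The call on Icos was lost under quantile normalization (adjusted p = 0.052). That on Tox was lost there (0.070) and without the variance trend (0.0535). Bcl6, the lineage-defining repressor of these cells, differed by 0.50 (SE 0.28, adjusted p = 0.50), and the ranges of the 2 groups overlapped. Its difference was 0.80 without lymphoma array 1, 0.21 without lymphoma array 2 and 0.25 without wild type array 2. The chemokine receptor Cxcr5 differed by 0.74 (SE 0.40, adjusted p = 0.48), also with overlapping ranges, by 1.24 without lymphoma array 1 and by 0.24 without lymphoma array 2. It differed by 1.13 without wild type array 1 and by 0.34 without wild type array 2. The cytokine Il21 differed by 0.75 (SE 0.88, adjusted p = 0.81), with 11.34 and 8.30 on the lymphoma arrays against 9.21 and 8.92 on the wild type arrays. Its difference was -0.77 without lymphoma array 1 and 2.28 without lymphoma array 2. The mean log2 fold change of the list was 0.49. It differed from that of other genes in limma's camera test (adjusted p = 0.00022), but gave adjusted p = 0.39 with an estimated correlation. Without lymphoma array 1 the mean was 0.17 (adjusted p = 0.21) and without lymphoma array 2 it was 0.82. Adjusted over the list alone, 6 genes rose. Markers of B cells and myeloid cells were lower on the same lymphoma arrays (list means -2.80 for B cells and -1.77 for macrophages and monocytes), here and beside each T cell, cell division, metabolic and response list that follows. With fewer such cells, T cell genes would rise alike, and Cd3d, Cd3e and Cd3g had a mean of 0.48. The follicular helper mean of 0.49 was therefore not separated from this change in cell mix.

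**Figure D2:**
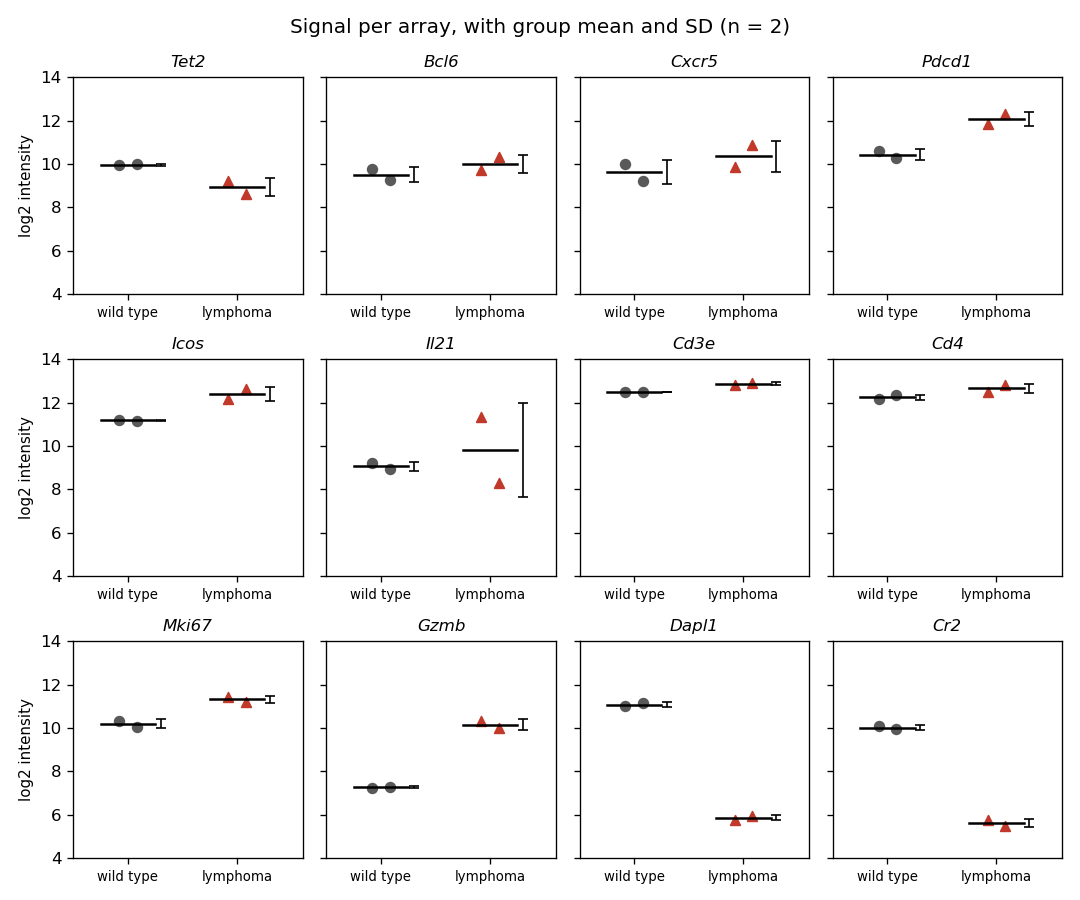
Log2 intensity (y axis) of 12 genes on each wild type array (grey circles) and each lymphoma array (red triangles), with group means as horizontal lines and SD as error bars (n = 2). Pdcd1, Icos, Mki67 and Gzmb are higher and Dapl1 and Cr2 lower on both lymphoma arrays, while Bcl6 and Cxcr5 overlap between groups and Il21 differs between the lymphoma arrays.

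Genes of naive and resting T cells were lower in lymphoma. Of 10 measured genes of this list, 5 fell and none rose, and all 10 had negative log2 fold changes. Beside Dapl1, Igfbp4 fell by 2.60, the egress receptor S1pr1 fell by 1.91 (adjusted p = 0.0056 in limma) and the quiescence factor Klf2 fell by 1.48. Across the 10 genes the mean was -2.09 (camera adjusted p = 2.1e-10; adjusted p = 0.32 with an estimated correlation). When adjusted over the list alone, 9 genes fell. The T cell receptor signalling list went both ways, with 2 of 17 measured genes lower, none higher and a mean of -0.22 (camera adjusted p = 0.82; mean -0.13 without lymphoma array 1), while 3 rose and 4 fell adjusted over the list alone. Themis, a protein needed for T cell selection in the thymus, was 2.83-fold lower (adjusted p = 0.0091) and Lat, the membrane scaffold of the receptor, fell by 1.06. Cd3e differed by 0.37 (adjusted p = 0.24) and Cd4 by 0.41 (adjusted p = 0.29), with both lymphoma values above both wild type values for each, and Cd4 by 0.27 without lymphoma array 2.

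Among the activation genes, 2 of 15 rose, the AP-1 factor Batf by 1.97 (adjusted p = 0.0068 in limma) and the costimulatory receptor Tnfrsf4 by 1.73. This list's mean of 0.35 did not pass (camera adjusted p = 0.075), and it passed without lymphoma array 1 (0.34, adjusted p = 0.046) and with Y-linked expression as a covariate (adjusted p = 0.033), a setting chosen after seeing the data. There were 4 rises and 1 fall adjusted over the list alone. Of 12 genes of inhibitory receptors and exhaustion, 3 rose and 1 fell. Lag3 rose by 1.53 beside Pdcd1 and Tox, and Cd244a fell by 2.26 (adjusted p = 0.0030). The list mean was 0.41 (camera adjusted p = 0.012; adjusted p = 0.51 with an estimated correlation). The call also ended under quantile normalization (0.0783), with array medians subtracted (0.0501), with the lowest tercile left out (0.0588) and without lymphoma array 2 (mean 0.26, adjusted p = 0.0878), while 6 genes rose and 2 fell adjusted over the list alone. Of 14 cytotoxic genes, 4 rose and 1 fell. Granzyme B, Gzmb, rose by 2.88 (SE 0.20, 7.38-fold, adjusted p = 0.0026), the protease inhibitor Cst7 by 1.29 and granzyme K, Gzmk, by 1.13, while the receptor Klrk1 fell by 1.25. The call on Gzmk was lost under quantile normalization (adjusted p = 0.066), and that on Klrk1 under quantile normalization (0.082), with array medians subtracted (0.078) and without the variance trend (0.054). The list mean was 0.53 (camera adjusted p = 0.0019; adjusted p = 0.32 with an estimated correlation), and adjusted over the list alone 7 rose and 2 fell. Beside the Cd3 mean of 0.48, the activation (0.35), exhaustion (0.41) and cytotoxic (0.53) means were not separated from the change in cell mix.

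The other T helper lists did not pass as a whole. Of 13 T helper 1 genes, the chemokines Ccl3 (2.34, adjusted p = 0.045 in limma) and Ccl4 (1.26) rose and the interleukin 12 receptor chain Il12rb2 fell by 1.87. The call on Ccl3 was lost under quantile normalization (adjusted p = 0.088), with array medians subtracted (0.053), without the variance trend (0.0535) and with the robust trend (0.14). Ccl4 was at an adjusted p of 0.0503 under quantile normalization. The list mean was 0.12 (camera adjusted p = 0.17) and it changed sign without lymphoma array 1 (-0.11), and it was 0.34 without lymphoma array 2. Over the list alone, 3 rose and 1 fell. No T helper 2 gene passed among 9 (mean -0.15, camera adjusted p = 0.36), with Ccr4 at -0.95 and Il4 at 0.87, and none passed over the list alone. Without lymphoma array 2 Ccr4 was at -1.50 and Il4 at 1.46, while without lymphoma array 1 they were at -0.39 and 0.28. With the probe sets below the median left out this mean became 0.098. No T helper 17 gene passed among 7 (mean 0.56, camera adjusted p = 0.43), and none passed over the list alone. Without lymphoma array 1 this mean was 1.04 (adjusted p = 0.0080), and without lymphoma array 2 it was 0.091 (adjusted p = 0.806). The interleukin 23 receptor Il23r differed by 3.06 (SE 1.28, adjusted p = 0.33) and Rora by 0.79. These differences were 5.27 and 1.37 without lymphoma array 1, and 0.85 and 0.20 without lymphoma array 2. Of 16 regulatory T cell genes, 3 rose and 1 fell, with the receptors Tnfrsf4 and Tnfrsf18 (0.94) and the cytokine subunit Ebi3 (1.65) higher and the G protein-coupled receptor Gpr83 lower (-1.83). The list mean was 0.18 and its median -0.08 (camera adjusted p = 0.22, towards higher). Without lymphoma array 1 the mean was -0.05, and without lymphoma array 2 it was 0.41 (adjusted p = 0.019). In the list-alone adjustment, 5 rose and 1 fell. Of 14 chemokine and egress receptors, Ccr8 rose by 2.92 (adjusted p = 0.010) while Ccr9 fell by 2.75 (adjusted p = 0.0021) together with S1pr1, and the mean was -0.22 (camera adjusted p = 0.37). It was -0.11 without wild type array 1, -0.34 without wild type array 2 and -0.13 without lymphoma array 1. Here 2 rose and 2 fell adjusted over the list alone. Of 6 measured alpha V segments of the T cell receptor, Trav19 fell by 1.55 (adjusted p = 0.022), the only call in either adjustment. The mean of these segments was -0.58 (camera adjusted p = 0.12). It was -1.05 (adjusted p = 0.0080) without lymphoma array 1, -0.10 without lymphoma array 2, -0.24 without wild type array 1 and -0.91 without wild type array 2, and the replicate block gave an adjusted p of 0.031. Trbv1 was the single measured beta V segment of its list and fell by 2.41 (adjusted p = 0.0099).

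Cell division genes were higher on the lymphoma arrays, the same arrays on which B cell and myeloid markers were lower (list means -2.80 and -1.77). Fewer B and myeloid cells would raise T cell genes alike, and Cd3d, Cd3e and Cd3g had a mean of 0.48. The mitosis mean of 1.23 (SD 0.20 across genes) lay above this, and it lay between 0.99 and 1.47 when 1 array was left out. The SD is across genes that vary together (estimated correlation 0.852), and an error across samples was not computed for either mean. If Cd3 expression per T cell was unchanged, the higher mitosis mean argues against such dilution as the only source of that rise. The DNA replication mean of 0.82 (SD 0.33 across genes) was not separated from dilution, and a different mix of T cell subsets was not tested. Of 19 measured mitosis genes, 8 rose, none fell and all 19 had positive log2 fold changes, and adjusted over the list alone all 19 rose. The kinetochore motor Cenpe and the checkpoint kinase Bub1 each rose by 1.54, the spindle motor Kif11 and the cyclin-dependent kinase Cdk1 by 1.44 each, and the proliferation marker Mki67 by 1.12 (SE 0.19, 2.17-fold, adjusted p = 0.030 in limma). Across the 19 genes the mean was 1.23 (camera adjusted p = 1e-16; adjusted p = 0.39 with an estimated correlation). Of 22 DNA replication genes, 5 rose and none fell, with the thymidylate synthase Tyms higher by 1.43 on the log2 scale, the DNA ligase Lig1 2.29-fold higher, the ribonucleotide reductase subunit Rrm2 higher by 1.18 and the polymerase subunit Pole by 1.18. The mean was 0.82 (camera adjusted p = 5.2e-15; adjusted p = 0.33 with an estimated correlation), and adjusted over the list alone 18 rose. Of 10 genes of DNA methylation and demethylation, Uhrf1, the partner of the maintenance methyltransferase, rose by 1.15 (adjusted p = 0.030) and none fell. This list's mean was -0.29 (camera adjusted p = 0.16). It was -0.58 (adjusted p = 0.0035) without lymphoma array 1, 0.0022 without lymphoma array 2 and -0.19 without wild type array 1. Over the list alone, 1 gene rose and 2 fell.

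Glycolysis genes were higher on the lymphoma arrays, with 7 of 14 measured genes up and none down. Markers of B cells (mean -2.80), macrophages and monocytes (-1.77) and dendritic cells (-1.93) were lower on the same arrays, and the rise was not separated from this change in cell mix. The lactate exporter Slc16a3 rose by 2.39, the triose isomerase Tpi1 by 1.97 (SE 0.20, 3.91-fold, adjusted p = 0.0064 in limma), the phosphoglycerate kinase Pgk1 by 1.37 and the mutase Pgam1 by 1.33. The list mean was 0.94 (camera adjusted p = 3.9e-09; adjusted p = 0.32 with an estimated correlation), and adjusted over the list alone 11 rose and 1 fell. Smaller shifts with no single gene past the threshold were found in 20 genes of oxidative phosphorylation and 14 of ribosome biogenesis. The former had a mean of 0.26 (camera adjusted p = 0.0011; adjusted p = 0.51 with an estimated correlation), with Ndufa1 at 0.55 and Atp5a1 at 0.46. This mean was 0.43 without wild type array 1 and 0.094 (adjusted p = 0.21) without wild type array 2, and Ndufa1 was at 0.85 and 0.25 in these 2 fits. The latter had a mean of 0.39 (camera adjusted p = 0.00036; adjusted p = 0.52 with an estimated correlation), with Dkc1 at 0.69 and Nop58 at 0.67. It was 0.21 (adjusted p = 0.105) without lymphoma array 1. Dkc1 (1.11, adjusted p = 0.011) and Nop58 (0.87, 0.044) passed without lymphoma array 2, and Dkc1 was at 0.26 without lymphoma array 1 and at 0.43 without wild type array 2. Neither list had a gene past the threshold over the list alone.

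Of 11 NF-kappaB targets, Tnfaip8 rose by 1.14 and the inhibitor Nfkbia by 0.92 (adjusted p = 0.028 in limma), and the mean was 0.56 (camera adjusted p = 8.3e-05; adjusted p = 0.32 with an estimated correlation), with 3 rises adjusted over the list alone. The probe sets of Tnfaip8 disagreed, and their average differed by 0.58 (adjusted p = 0.16). No interferon response gene passed among 16 in limma, with Oas2 at -1.10 and Mx1 at 1.00, while 3 rose and 1 fell adjusted over the list alone. Without lymphoma array 2 both passed (adjusted p = 0.0285 and 0.0096), without lymphoma array 1 Oas2 passed (0.0227), and with the replicate block Mx1 passed (0.048). Oas2 was at -0.67 without wild type array 1 and Mx1 at 0.57 without wild type array 2. The interferon list had a mean of 0.27 (camera adjusted p = 0.032; adjusted p = 0.58 with an estimated correlation). The call ended under quantile normalization (0.0804), with array medians subtracted (0.0568), and with the lowest tercile (0.195) or the values below the median (0.374) left out. It also ended without wild type array 2 (mean 0.076, adjusted p = 0.255) and without lymphoma array 1 (mean 0.089, adjusted p = 0.441), while the mean was 0.47 without wild type array 1 and 0.46 without lymphoma array 2. No p53 target passed among 10 (mean 0.17, camera adjusted p = 0.12), with Zmat3 at 0.71 and Phlda3 at 0.60, and none passed over the list alone. Phlda3 passed without lymphoma array 1 (adjusted p = 0.038), and without lymphoma array 2 it was at 0.34 and the list mean was 0.10. No gene of the unfolded protein response passed among 13, with Herpud1 at -0.92 and Pdia6 at 0.72, and none passed over the list alone. This mean was -0.02, the camera test pointed to higher (adjusted p = 0.99), and the mean became 0.054 with array medians subtracted, 0.066 without wild type array 1 and 0.037 without lymphoma array 1. It was -0.11 without wild type array 2 and -0.081 without lymphoma array 2. Herpud1 passed under quantile normalization (adjusted p = 0.043) and without lymphoma array 1 (0.016). Immediate early and heat shock genes, which respond to handling of cells, had no call among 11 in either adjustment and a mean of -0.01 (camera adjusted p = 0.77), which became 0.070 with array medians subtracted. It was -0.39 (adjusted p = 0.028) without wild type array 1, 0.37 without wild type array 2, -0.21 without lymphoma array 1 and 0.19 without lymphoma array 2. Hsph1 was at 1.07 and Hspa1a at 0.79, the latter with overlapping ranges. Both passed without lymphoma array 2 (adjusted p = 0.0014 and 0.0054), where Hspa1a was at 2.02. It was at -0.43 without lymphoma array 1 at -0.19 without wild type array 1 and at 1.77 without wild type array 2, and Hsph1 passed with the Y-linked covariate (0.045).

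Markers of several other spleen cell types were lower on the lymphoma arrays. Of 13 B cell genes, 11 fell and all 13 had negative log2 fold changes (mean -2.80, camera adjusted p = 2.6e-16; adjusted p = 0.32 with an estimated correlation). All 13 fell when adjusted over the list alone. Beside Cr2 and Fcer2a, the transcription factor Ebf1 fell by 3.42 and the adaptor Bank1 fell by 3.39. Of 11 immunoglobulin segments, 8 fell and none rose (mean -4.06, camera adjusted p = 1.5e-13; adjusted p = 0.32 with an estimated correlation), and 10 fell when adjusted over the list alone. The log2 difference was -5.42 for Igkv4-55, -5.37 for Igkv9-120, -5.28 for Igha and -5.12 for Igkv19-93. With the robust variance trend the adjusted p of these 4 and of Jchain and Bank1 lay between 0.0874 and 0.241. Of 9 plasma cell genes, 3 fell, namely Jchain, the chaperone Mzb1 (-2.43) and the survival receptor Tnfrsf17 (-1.88). The plasma cell list passed (mean -1.30, camera adjusted p = 0.00026; adjusted p = 0.43 with an estimated correlation), and 5 fell over the list alone.

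Of 16 macrophage and monocyte genes, 13 fell in both adjustments and none rose (mean -1.77, camera adjusted p = 1.05e-17; adjusted p = 0.32 with an estimated correlation). The iron exporter Slc40a1 fell by 3.33 and the macrophage receptor Adgre1 fell by 3.22 (SE 0.17, adjusted p = 0.0015 in limma), with the mannose receptor Mrc1 at -2.74 and the growth factor receptor Csf1r at -2.51. Of 9 dendritic cell genes, 6 fell in both adjustments and none rose (mean -1.93, camera adjusted p = 1.4e-10; adjusted p = 0.32 with an estimated correlation), with the cytokine receptor Flt3 at -3.19, the integrin Itgax at -2.72 and the lectin Siglech at -2.60. Of 8 genes of MHC class II presentation, 7 fell (8 over the list alone; mean -1.82, camera adjusted p = 8.2e-11; adjusted p = 0.32 with an estimated correlation), with H2-Ob at -3.06, the transactivator Ciita at -2.41, H2-Aa at -1.79 and H2-Oa at -1.69. Of 7 genes of CD8 T and NK cells, only Tyrobp, an adaptor that myeloid cells also use, passed (-2.87), and 4 fell over the list alone. The mean was -1.02 (camera adjusted p = 0.00057; adjusted p = 0.33 with an estimated correlation; mean -1.75 with the values below the median left out), and Cd8a was at -1.11 (adjusted p = 0.105). Cd8a passed with the replicate block (0.026) and without lymphoma array 1 (-1.38, adjusted p = 0.0027).

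The remaining cell type lists did not pass. Of 13 neutrophil genes, Ngp rose by 1.49 and Mmp9 fell by 1.78 (adjusted p = 0.0056 in limma; mean 0.05, camera adjusted p = 0.36). The mean was -0.035 without wild type array 1 and 0.14 without wild type array 2, and 1 rose and 2 fell over the list alone. No gene passed among 11 erythroid genes (mean 0.20, camera adjusted p = 0.34), with Rhag at 1.13 and Slc4a1 at 0.73. Without lymphoma array 1 that mean was 0.48 (adjusted p = 0.0098), and without lymphoma array 2 it was -0.085. Without lymphoma array 1 Rhag was at 1.78 and Slc4a1 at 1.55, and without lymphoma array 2 they were at 0.47 and -0.099. No gene passed among 6 genes of megakaryocytes and platelets (mean -0.16, camera adjusted p = 0.33), with Vwf at -0.32 and Treml1 at -0.26. This mean was -0.33 without wild type array 1, -0.0011 without wild type array 2, -0.046 without lymphoma array 1 and -0.28 without lymphoma array 2. Vwf was at -0.18 without wild type array 2, and Treml1 at -0.43 without lymphoma array 1 and at -0.090 without lymphoma array 2. No stromal or endothelial gene passed among 10. That list's mean was 0.05, its median was -0.17 and the camera test pointed to lower (adjusted p = 0.14), with Dcn at 2.71 (SE 1.64) and Pecam1 at -0.88. The mean was -0.26 without lymphoma array 1, 0.36 without lymphoma array 2 and 0.032 without wild type array 2. Dcn was at -0.18 without lymphoma array 1 and at 5.59 without lymphoma array 2, where Pecam1 was at -0.98. Over the list alone, no gene of the erythroid and platelet lists passed and 1 stromal or endothelial gene fell.

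**Figure D3:**
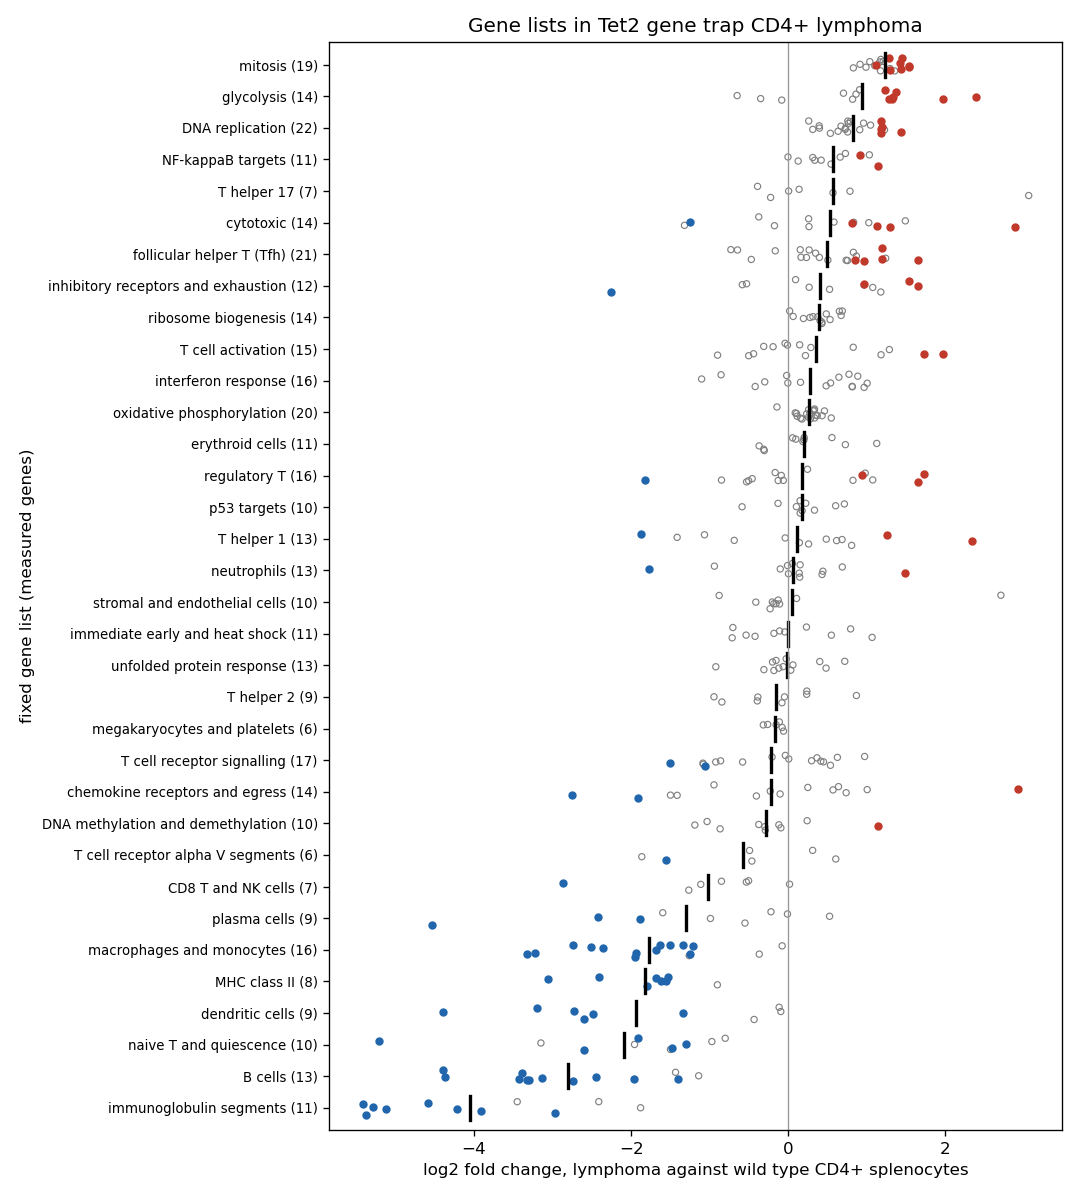
Log2 fold change of lymphoma over wild type (x axis) for the measured genes of each fixed list (y axis, number of genes in brackets), with black bars at list means. Filled red and blue points are genes higher and lower at an adjusted p under 0.05 in limma, open points did not pass, and mitosis (mean 1.23) and immunoglobulin segments (mean -4.06) stand at the extremes.

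Of 35 lists tested with camera at a preset correlation, 18 passed an adjusted p of 0.05, 10 towards higher and 8 towards lower expression. With the correlation estimated from these arrays none passed in camera, and 2 had an unadjusted p under 0.05. That setting also called 0 of 10 shifted lists in simulated data whose genes varied independently. The cytotoxic list had an estimated correlation of -0.0034, below the preset 0.01, yet its unadjusted camera p went from 0.00088 to 0.0715. Correlation alone therefore does not account for the loss, and a list that did not pass there is not shown to be unshifted. The rotation test fry, which asks whether a list's genes move one way, passed 2 lists, those of macrophages and monocytes and of dendritic cells. When fry asked for change in either direction, 22 lists passed.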

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

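The tests of explanations given here were all chosen after the results they bear on had been seen, while the test of all probe sets and that of the sex-linked list were planned. Outside the named genes, 13 probe sets without a single annotated gene were higher in lymphoma at an adjusted p under 0.05 when all probe sets were tested, and 50 were lower. They were picked out because they lie outside the genes the comparison used. All 13 had no gene in the annotation, as did 36 of the 50, while the other 14 had several symbols. No explanation was tested for them.

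The sex-linked genes did not follow the groups. Xist, which is transcribed from the inactive X chromosome in female cells, had intensities of 5420 and 42 on wild type arrays 1 and 2 and of 1860 and 4690 on lymphoma arrays 1 and 2. The Y-linked gene Eif2s3y had 12.8, 368, 843 and 13.9 on the same arrays, Uty 15.3, 580, 754 and 21.3, and Kdm5d 40.3, 407, 530 and 37.1. Lymphoma array 1 therefore carried both, and each group held 1 array with low and 1 with high Y-linked signal. The mean of these 4 genes was 0.96 (camera adjusted p = 0.541; no gene passed in either adjustment), -0.73 without lymphoma array 1 and 2.66 (adjusted p = 0.010) without lymphoma array 2. It was 0.16 without wild type array 1 and 1.76 without wild type array 2. With Y-linked expression as a covariate, chosen after seeing the data and defined from genes of this list, the list passed (adjusted p = 0.0415).

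A mixture of normal female CD4+ splenocytes into a male sample would need a share of 36.2% to give the Xist signal of lymphoma array 1. The female level behind this share was 5050, the mean of wild type array 1 and lymphoma array 2, so a lymphoma array helped set it. Of 35 genes high in wild type cells and low on lymphoma array 2, 34 lay below the level this share needs. The median difference was -1.38 on the log2 scale (scaled median absolute deviation 0.763), which argues against such cells at that share. Cr2 and Adgre1 were among the 35, so B cell and myeloid genes were included. The test covers cells as collected for the wild type arrays, not purer T cells. Cells of a female lymphoma, or Xist made by the male cells, cannot be told apart, because the tumour's own Y-linked level is not known. The Y-linked genes of lymphoma array 1 differed from those of wild type array 2 by 0.651 on average (SD 0.472, n = 3 genes). No biological explanation was tested.

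For the lower B cell, dendritic cell and macrophage genes, array scaling was weighed first. The B cell mean stayed at -2.73 or below under the other scalings. The array medians already lay between 7.02 and 7.15 on the log2 scale, so subtracting them could move this mean only slightly. The closeness of the medians, rather than the rescaled mean, argues against a difference in scale as the source. Fewer carried-over cells on the lymphoma arrays would lower every other cell type, and the median was below 0 in 4 of the 4 types with at least 3 markers of a mean log2 value of at least 8 over all arrays, from -0.551 for plasma cells to -3.13 for B cells. The other 5 types had too few such markers, and over all measured genes, mostly at low signal, their medians were 0.139 for neutrophils, 0.187 for erythroid cells, -0.85 for CD8 T and NK cells, -0.169 for stromal and endothelial cells and -0.134 for megakaryocytes and platelets. Fewer such cells cannot be told apart from a difference between lymphoma and normal spleen, which was not tested, because cell composition goes with the groups.

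For the lower naive T cell genes, B and myeloid cells on the wild type arrays were weighed. Such cells would dilute T cell genes on the wild type arrays, so T cell genes would appear higher in lymphoma. Lef1, Il7r, Dapl1 and Igfbp4, picked as genes those cells lack, had a mean of -2.52, with -0.972 the smallest fall. Cd3d, Cd3e and Cd3g had a mean of 0.48, a difference of -3 (SE 0.964 across genes, not samples). This argues against the explanation for these 4 genes, of which Dapl1 and Igfbp4 had the largest called falls of the list. The list's other genes, such as S1pr1 and Klf2, were not covered. A change of T cell state in the lymphoma may account for the fall and remains a hypothesis, and a different mix of T cell subsets was not tested.

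The lymphoma arrays differed from each other by over 1 log2 unit in 780 genes and the wild type arrays in 216, and the median absolute difference was 0.895 times that of the wild type pair in genes of the lowest tercile of level, 1.09 times in the middle and 0.965 times in the highest. By bounds set before the ratios were computed, noisier lymphoma arrays needed a clearly raised ratio in the lowest tercile, which was not seen. Ruling noise out also needed a raised ratio in the highest, so the test as set did not decide. The ratios argue against lymphoma arrays noisier across genes in general. Differences of over 2 log2 units occurred in 173 genes between the lymphoma arrays and 8 between the wild type arrays. Noise confined to some genes was not tested.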

How the results depend on the processing

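Y-linked expression as a covariate was chosen after seeing the data, and the other alternatives before. Without a detection call, signal over background limits dim genes to an unknown extent. The counts of 362 higher and 490 lower genes ranged from 0 to 1057 and from 0 to 843 when 1 array was left out. Both counts were 0 in limma without either wild type array, where the lowest adjusted p was 0.0616 or 0.0506 and 2 arrays of lymphoma set the spread. An adjusted p under 0.10 gave 665 higher genes, and testing all probe sets gave 138 and 301. The other alternatives kept both counts within 1.5 times. Of 85 called named genes, 6 lost the call under quantile normalization, 2 with array medians subtracted, 3 without the variance trend, 9 with the robust trend and 1 with probe sets averaged. The cause was not tested.

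Replicate numbers are shared between groups, but with only 2 pairs and r = 0.228 between deviations across genes, nothing shows that they pair the samples. The replicate block gave 429 higher and 555 lower genes, with 798 of the 852 shared, and 19 lists. Among the named genes and lists it added calls on Cd8a, Mx1 and the alpha V segments and ended none. The Y-linked covariate gave 380 and 492, with 749 shared.

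Tet2 ranged from -1.324 to -0.7432 and the follicular helper mean from 0.1664 to 0.8161 when 1 array was left out. That mean of 0.4913 did not pass with an estimated correlation or with fry (adjusted p = 0.392 and 0.195). The 18 lists past the threshold became 0 with an estimated correlation and 2 with fry, and 16 to 20 in all other settings.

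Of list means, unfolded protein response (0.05433) and immediate early and heat shock (0.07002) changed sign with array medians subtracted, and T helper 2 (0.09814) with probe sets below the median left out. With 1 array left out, means ranged from -0.1122 to 0.3439 for T helper 1, -0.05278 to 0.4061 for regulatory T, -0.579 to 0.002157 for DNA methylation, -0.1108 to 0.0659 for unfolded protein response, -0.03475 to 0.1438 for neutrophils, -0.08452 to 0.4769 for erythroid cells, -0.263 to 0.3644 for stromal cells, -0.3874 to 0.3739 for immediate early genes and -0.7342 to 2.657 for sex-linked genes. Single genes ranged from -0.09888 to 1.552 for Slc4a1, -0.1761 to 5.588 for Dcn, -0.4312 to 2.018 for Hspa1a and -0.7662 to 2.275 for Il21. The cause was not tested.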

Other observations

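Genes that differed between the lymphoma arrays were looked up after the comparison, and the genes named in this paragraph were chosen after their values were seen. Kcnma1, a potassium channel subunit, had log2 values of 13.4 and 5.70 on lymphoma arrays 1 and 2, against 9.48 and 10 on the wild type arrays. Dcn had 11.4 and 5.67 (wild type 5.91 and 5.78) and the calcium channel subunit Cacna1d 11.2 and 6.51 (wild type 8.54 and 8.65). The reverse held for the T cell receptor segment Trav14-1, with 5.20 and 11.4 (wild type 7.95 and 7.44), the receptor Olr1, with 5.56 and 10.5, the adaptor Grb10, with 5.64 and 10.2, Il23r, with 7.29 and 11.7, and the cytokine Il6, with 3.64 and 7.51. With 1 array of each kind these differences have no replicate check.

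Both hypotheses that follow rest on gene lists written after Ak4, Psat1 and Slc1a4 had been seen among the high-ranking genes, while the bounds of each test were set before its value was computed. A wider hypoxia response was a hypothesis for the higher glycolysis genes. Of 18 hypoxia targets outside glycolysis none passed and 14 were positive, with a mean of 0.355 (fry p = 0.126; camera adjusted p = 0.0080, adjusted p = 0.329 with an estimated correlation), so the test does not decide. Higd1a was at 1.06 and Ero1a at 1.02. A wider response of amino acid synthesis and uptake was a hypothesis for the higher Psat1 and Slc1a4. Of 12 other measured genes 1 passed, the asparagine synthetase Asns (1.46, adjusted p = 0.041 in limma), with a mean of 0.327 (fry p = 0.281; camera adjusted p = 0.0409, adjusted p = 0.452 with an estimated correlation), and this too stays open.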
